A study of Homo sapiens with 4 samples.

How the data were processed

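Gene expression was measured by RNA sequencing in HEK293T cells, an established human embryonic kidney cell line, in 4 libraries. Per the labels, 2 libraries came from cells overexpressing Flag, the epitope tag used as control, and 2 from cells overexpressing RNase H1, the enzyme that degrades the RNA strand of RNA-DNA hybrids. The series to which they belong maps R-loops, structures in which RNA pairs with 1 strand of the DNA duplex. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS mRNA-seq V3 kit. Nothing in the labels says that replicates came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical.

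The authors deposited 1 table of TPM, the share of each transcript in its library scaled to a common total, with a column per library. Per the submitters' processing notes, STAR and the hg38 build were used. Their versions, the quantification program, the gene annotation release and any use of strand are not given in the sources used here. The table listed 38972 genes, of which 14067 were named by an Ensembl identifier and the rest by symbol. Library columns summed to 998921, 998901, 998936 and 998955 TPM. In 15 genes values had more than 2 decimals, as the mean of several entries would give. TPM keeps no sequencing depth, so the depth is unknown and no counting interval was computed. Mitochondrially encoded genes were not analysed here. A TPM value is a share of the transcripts in its library, so a change in total RNA per cell cannot be read from it.

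Genes with a mean of at least 1 TPM over the 4 libraries were tested, which left 15651. Values were taken as log2(TPM + 1) and compared between groups with limma 3.58.1 in R 4.3.3 (a linear model with a group term and moderated variances that follow an intensity trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 counted as a call. Log2 fold changes are on the log2(TPM + 1) scale unless another pseudocount is named. The added 1 makes them smaller in size than the ratio of the TPM values, most at low TPM. Errors of log2 fold changes are standard errors from this model, and errors of TPM are standard deviations over 2 libraries. The procedure was tested on simulated values for the same 15651 genes, with noise independent between genes. The noise took each gene's variance after moderation, which differs less between genes than before it, so recovery may be overstated. The changed genes were drawn only from those of about 5 TPM or more, so recovery at lower levels was not tested. Of 100 genes changed by 1 on the log2 scale 100% were called, and of 100 changed by 0.5 74% were called. Of the 188 calls in that simulation 14 were false, and simulated values without any change gave 1 call.

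Before the data were examined, 35 gene lists were fixed, and the 31 with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. With that preset, camera's p rests on genes as its units and not on the spread between libraries. Beside it stand camera with an estimated correlation and fry, which tests a list for change without comparing it with the other genes. Members were counted as called over all genes and again with p adjusted over the list alone. The rule for named genes was also fixed then. It took RNASEH1, the 8 genes with the largest increase and the 8 with the largest decrease among calls with a mean of at least 5 TPM and no overlap between groups, and from each list up to 4 members with the smallest p. Other genes named in the text, and the members given as further examples, were chosen after their values were seen. Some genes that the rule or the lists include are not reported here.

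Coordinates, gene spans, exon lengths and the GC content of the longest transcript came from GENCODE release 29 on GRCh38, matched by identifier for 11059 genes, by current symbol for 24636 and by the release's own symbol for 167, with 3110 unmatched. Of the tested genes 97.8% had a gene model. Genes with near-identical copies (RFPL4A, histones, ribosomal proteins, NPM1) and genes that overlap others (SAPCD1) may share reads, and their values are uncertain.

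Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 TPM, quantile normalization, median-of-ratios scaling, rescaling without RNASEH1, variances without an intensity trend, robust variances, the replicate number as a block, a minimum change of 2-fold, and leaving out each library. Corrections for GC content, and for GC content with exon length and gene span (splines with 4 degrees of freedom on each library's deviations), were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.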

Results

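RNA was sequenced from HEK293T cells in 2 libraries labelled Flag and 2 labelled RNase H1. Values above 0 were listed for 23556 and 23621 genes in the libraries labelled Flag and for 24585 and 24568 genes in those labelled RNase H1. Over the tested genes, log2 values correlated at 0.99 within the Flag group and within the RNase H1 group, and at 0.98 for each pair across groups. No pair of libraries was a duplicate, since at most 0.422% of the tested genes had identical values in any pair. The only comparison in the design asks which transcripts differ when RNase H1 is overexpressed in place of Flag.

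The TPM listed for RNASEH1, the gene that encodes RNase H1, was not higher in the libraries labelled RNase H1. RNASEH1 (chromosome 2, 3544793 to 3558616, minus strand, GENCODE release 29 on GRCh38) stood at 32.09 and 32.8 TPM in the libraries labelled Flag (32.4 ± 0.502, SD, n = 2) and at 29.93 and 29.67 TPM in those labelled RNase H1 (29.8 ± 0.184, SD, n = 2). Its log2 fold change was -0.12 with a standard error of 0.06 and a 95% interval from -0.27 to 0.04 (limma adjusted p = 0.260). The upper bound of that interval corresponds to a 1.03-fold level. RNASEH1-DT, the divergent transcript beside it, fell from 11.3 ± 1.19 to 7.84 ± 0.219 TPM (log2 -0.47 ± 0.11, SE, limma adjusted p = 0.0471). That call was lost after GC correction and under quantile normalization. The sample titles abbreviate the RNase H1 group as oeRNH1, and the separate gene with the symbol RNH1 was not higher either. RNH1 stood at 55.8 ± 1.58 TPM in the libraries labelled Flag and at 54.9 ± 4.79 TPM in those labelled RNase H1 (log2 -0.02 ± 0.07, SE, limma adjusted p = 0.857). Because the measured RNASEH1 level does not bear out the labels, groups are called by their labels throughout, and every direction below is that of the libraries labelled RNase H1 relative to those labelled Flag.

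ETV5, ANKRD1 and FOS were among the strongest increases, and MYC and IRS4 among the strongest decreases. ETV5, an ETS transcription factor (chromosome 3, 186046308 to 186110318), rose from 2.12 ± 0.431 to 14.1 ± 0.212 TPM (SD, n = 2; log2 2.28 ± 0.14, SE). ANKRD1, a YAP target and titin-binding protein (chromosome 10, 90912096 to 90921276), rose from 5.99 ± 0.120 to 27.8 ± 1.23 TPM (log2 2.04 ± 0.09), and FOS, an AP-1 subunit (chromosome 14, 75278774 to 75282230), from 4.08 ± 0.283 to 17.4 ± 1.57 TPM (log2 1.85 ± 0.11). MYC, the transcription factor of growth and ribosome synthesis (chromosome 8, 127735434 to 127741434), fell from 78.5 ± 2.09 to 30.3 ± 1.36 TPM (log2 -1.34 ± 0.06). IRS4, an insulin receptor substrate (chromosome X, 108732482 to 108736409), fell from 217 ± 0.721 to 103 ± 4.74 TPM (log2 -1.07 ± 0.05).

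Among the other genes with the largest increases were CGA, the shared subunit of glycoprotein hormones, at log2 1.97 ± 0.15, and GCNA, a germ cell nuclear protein, at 1.86 ± 0.15. RFPL4A rose by 1.95 ± 0.12 and has a near-identical copy, so its value is uncertain. RMRP, a short noncoding RNA, had a log2 fold change of 2.29 ± 0.50 and unequal values of 9.125 and 2.245 TPM in the libraries labelled Flag. Its values are among those with more than 2 decimals, as the mean of several entries would give, and are uncertain. ENSG00000288708, which has no symbol in the table, was listed at 0 in both libraries labelled Flag and at 46.9 and 56.9 TPM in those labelled RNase H1. Besides MYC and IRS4, the largest decreases were ENSG00000287064 (log2 -1.59 ± 0.13), SAPCD1 (-1.34 ± 0.18), PPFIA4, a liprin (-1.28 ± 0.23), ENSG00000280320 (-1.22 ± 0.25), ABCA2, a lipid transporter (-1.22 ± 0.08), and MACROD1, an ADP-ribosyl hydrolase (-1.08 ± 0.20). SAPCD1 overlaps a readthrough gene and its value is uncertain. Adjusted p for these genes lay between 0.000149 and 0.0397 (limma).

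**Figure D1:**
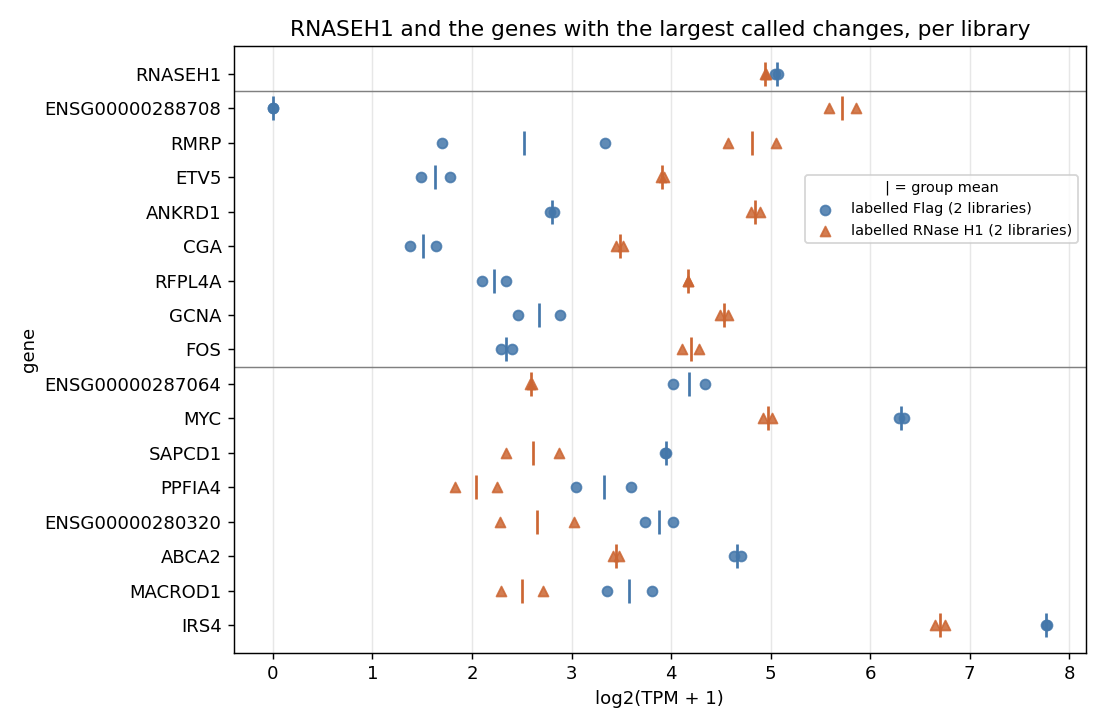
TPM on a log2(TPM + 1) axis for RNASEH1 (top), the 8 genes with the largest increase (middle) and the 8 with the largest decrease (bottom). Circles are the 2 libraries labelled Flag, triangles the 2 labelled RNase H1 and vertical ticks the group means. In each gene except RNASEH1 the gap between groups passed the limma test, and RNASEH1 was at 32.4 TPM in the libraries labelled Flag against 29.8 TPM.

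Of the 15651 tested genes, 1853 passed limma at the adjusted threshold, 986 higher and 867 lower. Most changes were small, with a median size of a called change of 0.42 on the log2(TPM + 1) scale. On that scale 118 calls (91 higher, 27 lower) reached 2-fold. Groups did not overlap in 60.7% of tested genes, where chance gives 33.3%. The number of calls was 1 without Flag replicate 1, 15 without Flag replicate 2, 0 without RNase H1 replicate 1 and 1 without RNase H1 replicate 2, fits that leave a single library in an arm and assume that it varies like the other arm. At an unadjusted p under 0.05 these fits had 3558, 3367, 3549 and 4035 genes. With no filter on low values the count was 0, and with variances that follow no intensity trend it was 1, against 5655 and 4337 genes at an unadjusted p under 0.05.

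Of the 31 gene lists, 12 passed camera, 9 upward and 3 downward. None passed with an estimated correlation, where 0 of 31 lists had an adjusted p under 0.05. That form of camera takes its degrees of freedom from the 4 libraries, and the preset form from the genes. With so few libraries hardly any list can pass it. The loss therefore does not show that correlation between genes accounts for the passes. Estimates lay on both sides of the preset 0.01, at -0.00856 for immediate early genes and 0.144 for the unfolded protein response. By fry 12 passed, 11 of them shared with camera.

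Immediate early genes, the transcripts that growth factors and stress induce within minutes, rose as a list (camera adjusted p = 2.84e-14, adjusted p = 0.362 with an estimated correlation). Of 31 tested members 20 were higher, 1 was lower and 10 were not called, and adjusted over the list alone 27 were higher and 1 lower. The median log2 fold change was 0.64. EGR1 rose from 3.41 to 12.2 TPM (log2 1.58 ± 0.11, SE, n = 2), ATF3 from 65.5 to 142 TPM (1.11 ± 0.05), and the growth-factor feedback inhibitors DUSP5 and SPRY2 by 1.02 ± 0.09 and 1.14 ± 0.10. ARC, FOSB and FOSL1 rose by 1.79 ± 0.23, 1.33 ± 0.14 and 1.40 ± 0.13. The member that fell was MYC. JUN, at log2 0.13 ± 0.05, did not pass (adjusted p = 0.113). Markers of carcinoma epithelium moved the same way, with a median of 0.25 over 8 tested members.

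Genes of the unfolded protein response, which folds and disposes of proteins in the endoplasmic reticulum, rose as a list (camera adjusted p = 1.37e-05, adjusted p = 0.382 with an estimated correlation). Of 24 members 11 were higher, 0 lower and 13 not called, and adjusted over the list alone 15 were higher and 0 lower. The chaperone HSPA5 rose from 397 to 548 TPM (log2 0.46 ± 0.04), DNAJB9 from 19.3 to 38.9 TPM (0.98 ± 0.07), MANF by 0.47 ± 0.04 and XBP1 by 0.52 ± 0.05. Genes of the heat shock response also passed (adjusted p = 0.0261, adjusted p = 0.382 with an estimated correlation), with 7 higher, 1 lower and 10 not called of 18, and 9 higher and 1 lower adjusted over the list alone. HSPA8 rose by 0.32 ± 0.03, DNAJA1 by 0.44 ± 0.04 and HSP90AA1 by 0.27 ± 0.03, and HSPE1, a mitochondrial chaperonin, fell by 0.22 ± 0.04. The heat shock list missed the threshold without Flag replicate 2 (adjusted p = 0.0781) and without RNase H1 replicate 2 (adjusted p = 0.0739).

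Interferon-stimulated genes rose as a list (camera adjusted p = 0.000400, adjusted p = 0.382 with an estimated correlation), with 5 of 19 members higher, 0 lower and 14 not called, and 7 higher and 0 lower adjusted over the list alone. IFI6 rose from 9.09 to 22.5 TPM (log2 1.22 ± 0.14), ISG15 from 5.33 to 13.2 TPM (1.16 ± 0.11), and HERC5 by 0.47 ± 0.08. Sensors of cytosolic nucleic acids did not pass (adjusted p = 0.75), with 1 higher, 0 lower and 7 not called of 8, and the same counts adjusted over the list alone. The higher member was the kinase TBK1 (0.31 ± 0.05), a call lost after GC, length and span correction. NF-kB and inflammatory genes missed the threshold (camera adjusted p = 0.0717, adjusted p = 0.525 with an estimated correlation). Of 12 members 1 was higher, 0 lower and 11 not called, and adjusted over the list alone 2 were higher and 0 lower. This list passed upward with no filter on low values (adjusted p = 0.0048), after GC correction (0.0397), after GC, length and span correction (0.0475), without Flag replicate 2 (0.0470) and without RNase H1 replicate 1 (0.0229), and its adjusted p over 17 settings reached 0.586. TNFAIP3, an NF-kB feedback inhibitor, was higher by 0.83 ± 0.19 (adjusted p = 0.0469), a call held in 7 of 18 settings and lost in 11.

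Genes of the G1/S transition and DNA replication rose as a list (camera adjusted p = 0.00229, adjusted p = 0.382 with an estimated correlation). Of 38 members 15 were higher, 1 lower and 22 not called, and adjusted over the list alone 17 were higher and 2 lower. CDC6, a replication licensing factor, rose from 83.3 to 132 TPM (log2 0.66 ± 0.05), CCNE2 from 21.8 to 39.1 TPM (0.82 ± 0.09) and PCNA by 0.29 ± 0.04. The list of mitotic genes did not pass (adjusted p = 0.59), with 2 higher, 3 lower and 29 not called of 34, and 3 higher and 3 lower adjusted over the list alone. CENPF and CENPE, proteins of the kinetochore, fell by 0.40 ± 0.05 and 0.66 ± 0.12. Replication-dependent histones passed upward (adjusted p = 0.00426, adjusted p = 0.382 with an estimated correlation), with 4 higher, 0 lower and 20 not called of 24, and 5 higher and 0 lower adjusted over the list alone. H2BC12 rose from 60.4 to 102 TPM (0.75 ± 0.07). Histone transcripts are mostly not polyadenylated and near-identical in sequence, and this list missed the threshold without RNase H1 replicate 2 (adjusted p = 0.0665) and lay below the other genes on average among genes of at least 5 TPM (mean difference -0.05, adjusted p = 0.156).

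Targets of p53 passed upward (camera adjusted p = 0.0103, adjusted p = 0.382 with an estimated correlation), with 8 higher, 0 lower and 19 not called of 27, and 9 higher and 0 lower adjusted over the list alone. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 34.7 to 52.2 TPM (log2 0.58 ± 0.06) and GADD45A from 56.2 to 89.1 TPM (0.65 ± 0.05). MDM2, at 0.17 ± 0.07, did not pass (adjusted p = 0.142), and neither did BAX (-0.02 ± 0.05) or BBC3 (-0.04 ± 0.09). The activity of p53 was not measured, so the rise of this list is not read as p53 output. Without Flag replicate 1 the p53 list missed the threshold (adjusted p = 0.0555). Genes of replication stress and DNA repair did not pass as a list (adjusted p = 0.215), with 5 higher, 1 lower and 32 not called of 38, and 7 higher and 2 lower adjusted over the list alone. CLSPN and CDC25A, of the replication checkpoint, rose by 0.62 ± 0.08 and 0.46 ± 0.05.

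The 3 lists that fell hold genes of metabolism and growth. Hypoxia and glycolysis genes fell (camera adjusted p = 0.000819, adjusted p = 0.382 with an estimated correlation), with 1 higher, 9 lower and 20 not called of 30, and 3 higher and 18 lower adjusted over the list alone. LDHA, lactate dehydrogenase A, fell from 805 to 518 TPM (log2 -0.63 ± 0.03), HK2, a hexokinase, from 28.8 to 18.1 TPM (-0.64 ± 0.08) and ENO1 by 0.23 ± 0.03, and the glucose transporter SLC2A3 rose by 0.72 ± 0.15. Nuclear-encoded subunits of the respiratory chain fell (adjusted p = 0.00426, adjusted p = 0.382 with an estimated correlation, fry adjusted p = 0.0627), with 1 higher, 10 lower and 37 not called of 48, and 1 higher and 12 lower adjusted over the list alone. ATP5MC1 fell by 0.57 ± 0.05 and NDUFV1 by 0.51 ± 0.05. Ribosome biogenesis genes fell (adjusted p = 0.00426, adjusted p = 0.382 with an estimated correlation), with 1 higher, 8 lower and 35 not called of 44, and 2 higher and 11 lower adjusted over the list alone. NHP2 fell by 0.33 ± 0.04, MYBBP1A by 0.43 ± 0.06 and FBL by 0.24 ± 0.05, and RRN3, an initiation factor of RNA polymerase I, rose by 0.46 ± 0.05.

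Factors that resolve R-loops did not pass as a list (camera adjusted p = 0.857). Of 27 members 1 was higher, 2 were lower and 24 were not called, and adjusted over the list alone 2 were higher and 2 lower. Their median of 0.04 and their mean difference from other genes of -0.01 had opposite signs. The helicases RTEL1 and PIF1 fell by 0.61 ± 0.12 and 0.58 ± 0.12 on the log2 scale. Their GC content was 62.5% and 61.6%, and both lost the call after GC correction. Genes of RNase H2 and ribonucleotide repair did not pass as a list (adjusted p = 0.424), with 4 higher, 1 lower and 3 not called of 8, and the same counts of calls adjusted over the list alone. RNASEH2C rose by 0.40 ± 0.07 and LIG1, a DNA ligase, fell by 0.58 ± 0.07, and the fold changes of RNASEH2A and RNASEH2B were -0.10 ± 0.06 and -0.17 ± 0.12. Genes whose loci are often used to measure R-loops by qPCR passed upward (adjusted p = 0.0218, adjusted p = 0.525 with an estimated correlation) with 2 of 9 higher, 0 lower and 7 not called, and 4 higher and 0 lower adjusted over the list alone. The higher members were APOE (0.57 ± 0.13) and EGR1, which is also an immediate early gene. Without RNase H1 replicate 1 this list missed the threshold (adjusted p = 0.0555).

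Genes of the integrated stress response and amino acid supply moved both ways and did not pass as a list (camera adjusted p = 0.965), with 4 higher, 4 lower and 27 not called of 35, and 9 higher and 9 lower adjusted over the list alone. DDIT3 rose by 0.78 ± 0.07 and SLC3A2 by 0.64 ± 0.05, and DDIT4 fell by 0.89 ± 0.05 and CBS by 0.67 ± 0.08. DNA methylation and demethylation genes missed the threshold (camera adjusted p = 0.0967, adjusted p = 0.525 with an estimated correlation). Of 16 members 4 were higher, 1 lower and 11 not called, and adjusted over the list alone 5 were higher and 1 lower. Their median log2 fold change was only 0.04, against a mean difference from the other genes of 0.21. This list passed by fry (adjusted p = 0.0226) and, by camera, after GC, length and span correction (adjusted p = 0.0398, with a range up to 0.261 over 17 settings). Within it GADD45B rose from 18.3 to 54.4 TPM (1.53 ± 0.11) and GADD45A, which also counts among the p53 targets, by 0.65 ± 0.05. DNMT3B, the member called lower, fell by 0.34 ± 0.07. Splicing factors (adjusted p = 0.903) had 5 higher, 5 lower and 29 not called of 39, and 9 higher and 7 lower adjusted over the list alone. CLK1 rose by 0.57 ± 0.07 and HNRNPA1 fell by 0.41 ± 0.04. Polycomb genes (adjusted p = 0.877) had 3 higher, 4 lower and 20 not called of 27, and 5 higher and 4 lower adjusted over the list alone. Transcription termination genes (adjusted p = 0.877) had 2 higher, 2 lower and 23 not called of 27, and 3 higher and 4 lower adjusted over the list alone.

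Cytosolic ribosomal proteins did not pass as a list (camera adjusted p = 0.965), with 6 higher, 1 lower and 71 not called of 78, and 9 higher and 3 lower adjusted over the list alone. Hosts of snoRNAs (adjusted p = 0.482) had 4 higher, 1 lower and 12 not called of 17, and 7 higher and 2 lower adjusted over the list alone, and SNHG15 rose by 0.63 ± 0.06. Genes of mitochondrial DNA replication and transcription (adjusted p = 0.843) had 2 higher, 2 lower and 19 not called of 23, with the same calls adjusted over the list alone, and TFB1M fell by 0.68 ± 0.08. Cholesterol synthesis genes (adjusted p = 0.75) had 0 higher, 2 lower and 22 not called of 24, and 0 higher and 0 lower adjusted over the list alone. Telomere genes (adjusted p = 0.262) had 2 higher, 2 lower and 13 not called of 17, and 2 higher and 4 lower adjusted over the list alone. Matrix and adhesion genes (adjusted p = 0.42) had 3 higher, 2 lower and 19 not called of 24, and 3 higher and 4 lower adjusted over the list alone. Neuronal genes (adjusted p = 0.965) had 1 higher, 3 lower and 12 not called of 16, with the same calls adjusted over the list alone, and the neurofilament gene NEFM fell by 0.52 ± 0.07.

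Markers of carcinoma epithelium passed upward by a small margin (camera adjusted p = 0.0466, adjusted p = 0.382 with an estimated correlation), with 3 higher, 1 lower and 4 not called of 8, and the same calls adjusted over the list alone. ANXA1, a phospholipid-binding protein, rose from 8.47 to 29.2 TPM (log2 1.68 ± 0.12), the keratins KRT18 and KRT8 by 0.27 ± 0.05 and 0.24 ± 0.05, and CDKN2A fell by 0.25 ± 0.06. This list missed the threshold without Flag replicate 1 (adjusted p = 0.0664), RNase H1 replicate 1 (0.0555) or RNase H1 replicate 2 (0.0957), and also with a pseudocount of 0.1 (0.0536), at a mean of at least 5 TPM (0.143) and under quantile normalization (0.0615). Fibroblast markers did not pass (adjusted p = 0.944), with 0 of 5 called either way over all genes and 0 adjusted over the list alone. Metallothioneins, blood markers and pluripotent stem cell markers had 3, 4 and 3 tested members, too few for the list test, and of these LIN28B fell by 0.26 on the log2 scale (adjusted p = 0.0492).

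**Figure D2:**
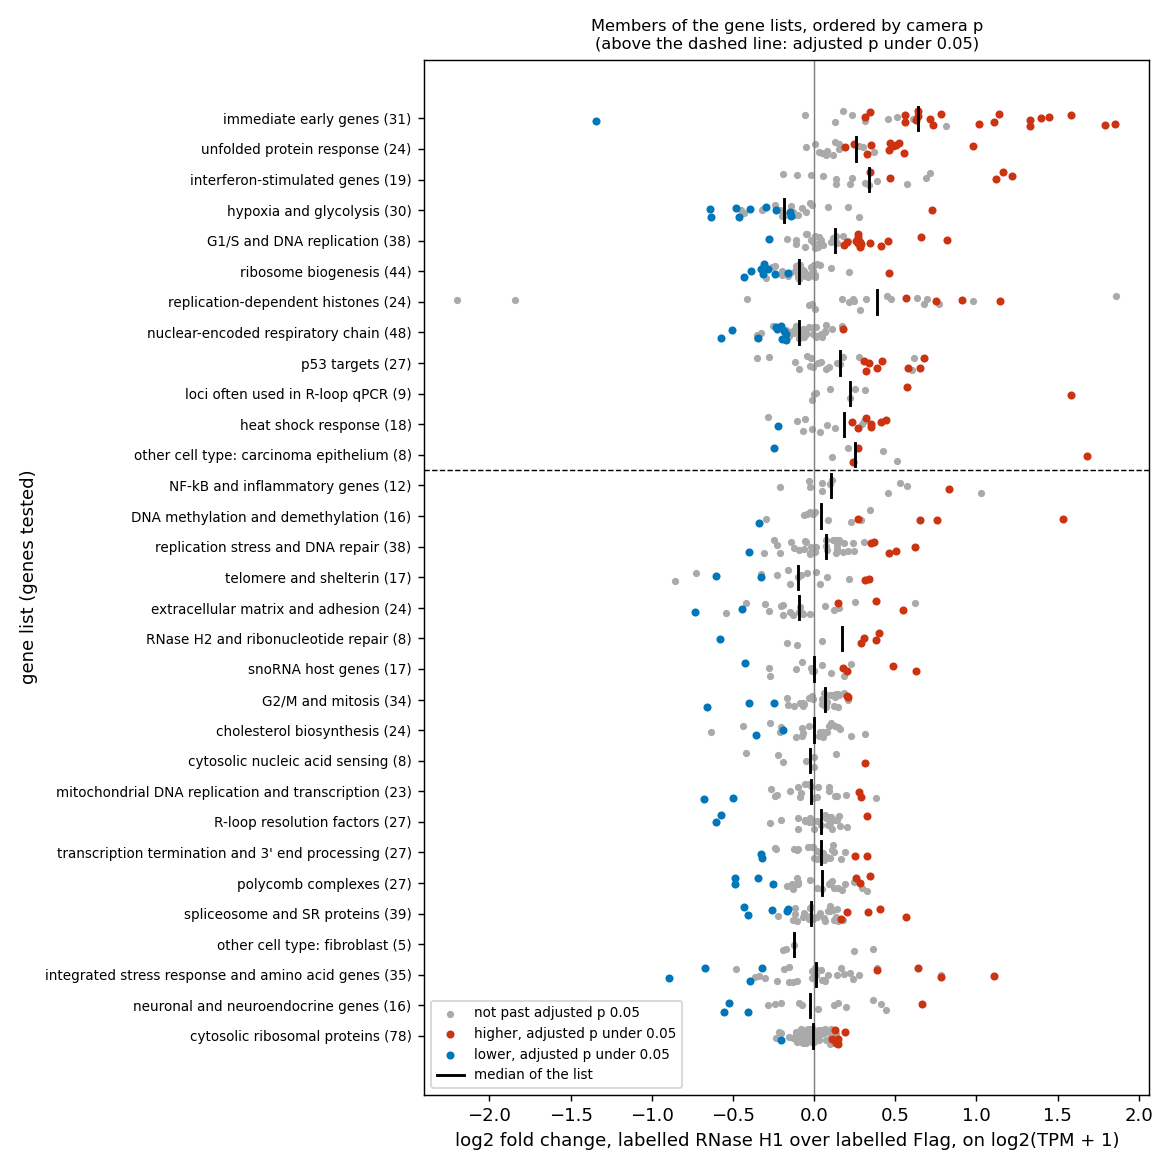
Log2 fold change of each tested member of the 31 gene lists, libraries labelled RNase H1 over those labelled Flag, on the log2(TPM + 1) scale, with lists ordered by camera p and the number of tested members in brackets. Red and blue points are members called higher and lower, grey points are not called, and black ticks are medians. Immediate early genes lie farthest to the right with a median of 0.64, and MYC is their single member called lower.

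Fold changes also followed the composition of the transcripts. Over genes with a gene model, the median log2 fold change went from 0.08 in the tenth with the lowest GC content to -0.12 in the tenth with the highest. Across genes, which are not independent replicates, the Spearman correlation of fold change with GC content was -0.219, and it was -0.0974 and -0.125 for the differences between libraries within the Flag and RNase H1 groups.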

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

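Corrections for GC content and for GC content with length and span were chosen after the data were seen. Each of the 1853 called genes present kept its sign in every setting, except under quantile normalization, where 1852 did. This is no separate support for the calls, since the settings reuse the same 4 libraries and some leave fold changes as they were. Calls also favour genes whose groups lie apart, so a reversal was unlikely from the start. The count of called genes moved more. With no filter on low values it was 0 (0 higher, 0 lower) and without an intensity trend 1 (1 higher, 0 lower), with 5655 and 4337 genes at an unadjusted p under 0.05. The prior degrees of freedom, which measure how far variances are shared between genes, were 1.95 and 2.01 in these fits against 4.09, and the cause was not tested further. A minimum of 2-fold on the log2(TPM + 1) scale left 118 (91 higher, 27 lower). Leaving out 1 library gave 0 to 15 calls (0 to 10 higher, 0 to 5 lower), with 3367 to 4035 genes at an unadjusted p under 0.05, in fits with fewer samples. Median-of-ratios scaling called 1867 genes, and the GC corrections 1548 and 1457, against 1972 in the same genes uncorrected. With the replicate number as a block the count was 2442. Deviations of libraries with the same number correlated at 0.0307, which gave no sign that the numbers pair the samples. This single correlation cannot exclude that samples of the same number were handled together. Rescaling without RNASEH1 removed only that gene, gives no value for it and left the same 1853 calls. Of 155 called genes followed across settings, 19 lost the call after GC correction, 27 after GC, length and span correction, 8 under quantile normalization, 3 under median-of-ratios scaling, 1 with robust variances and 1 with a pseudocount of 0.1. Those in the text were CDKN2A, FBL, PIF1, RTEL1, RNASEH1-DT, TNFAIP3 and TYMS after GC correction, these and MACROD1, NRXN3, RAD51B, RMRP and TBK1 after the fuller correction, KRT8, RNASEH1-DT, TNFAIP3 and TYMS under quantile normalization, TNFAIP3 and TYMS under median-of-ratios scaling, RMRP with robust variances and LIN28B with that pseudocount. The RNASEH1 log2 fold change lay between -0.14 and -0.10 in the other settings and passed in none of them.

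The count of lists past the threshold was 0 with an estimated correlation and 9 to 14 in the other settings, where 7 of the 12 lists passed in each of 17 camera fits. NF-kB genes, not among the 12, passed in 6 of these fits, the replicate block among them (adjusted p = 0.0368), and DNA methylation genes in 1. Differences of a list's mean from the other genes that changed sign were small. They were 0.0333 for neuronal genes with a pseudocount of 0.1, and 0.00154 for R-loop factors and -0.00673 for fibroblast markers with a pseudocount of 5. With no filter they were 0.0456 for nucleic acid sensing, -0.000515 for mitotic genes, -0.00274 for termination, 0.0356 for neuronal genes and -0.0267 for fibroblast markers. At 5 TPM or more they were 0.00681 for nucleic acid sensing, -0.0545 for histones, which had passed upward, and -0.000214 for the integrated stress response. Quantile normalization gave 0.00931 for ribosomal proteins, -0.00169 for mitotic genes, -0.00608 for termination and 0.000151 for neuronal genes. GC correction gave -0.0192 for mitotic genes, -0.0187 for splicing factors, -0.00927 for termination and 0.0223 for neuronal genes, and with length and span these were -0.0455, -0.0333, -0.0203 and 0.0447. Without 1 library, R-loop factors ranged from -0.0279 to 0.00659, ribosomal proteins from -0.0215 to 0.0115, neuronal genes from -0.0321 to 0.0269, mitotic genes from -0.00969 to 0.0286, fibroblast markers from -0.015 to 0.0604 and splicing factors from -0.00696 to 0.0272. The cause was not tested. Depth is unknown for TPM, so what it limits was not computed.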

Other observations

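None of the tests below was among those fixed before the data were examined, and the patterns they address were seen in the data. This includes the tests on long genes, on GC content and length and on MYC targets. Tests on the RNASEH1 level, on differences between libraries of a group and on cells of another type were chosen with their results already seen. So were those on ERK output and on YAP and TAZ targets. The genes named here and the gene lists for ERK, YAP and TAZ, and MYC were also chosen after the results were seen.

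The longest genes were lower in the libraries labelled RNase H1. Genes spanning at least 200 kb (1042 tested) had a median log2 fold change of -0.11, against 0.01 in the 14268 others (camera p = 1.91e-05, p = 0.113 with an estimated correlation). Only the 15310 genes with a gene model entered this fit, and its calls were adjusted over them. Of the long genes 24 were called higher and 89 lower, and of the others 1017 higher and 842 lower. In the 171 genes of at least 500 kb the median was -0.19. SMYD3, a lysine methyltransferase gene of 758 kb, fell from 11.4 to 5.3 TPM (log2 -0.98 ± 0.13, SE, n = 2), SCFD2 from 12.9 to 6.55 TPM (-0.88 ± 0.10), UBE2E2 from 63.8 to 35.0 TPM (-0.85 ± 0.15), and RAD51B, NRXN3 and TENM1 by 0.76, 0.75 and 0.73. The long genes BMPER and FILIP1L rose by 1.03 ± 0.16 and 1.02 ± 0.12.

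Of the technical explanations for lower long genes, removing each library's GC trend left their median at -0.138, and removing its trend with exon length left it at -0.0875, so neither trend accounts for the whole difference. Camera p with an estimated correlation was then 0.0353 and 0.0464, so whether it fell under 0.05 depended on the correction. Between libraries of a group the median difference of these genes was at most 0.0400 in size, smaller than that between groups. RNA quality and speed of elongation were not tested, and an effect of the overexpressed protein stays open, untested, since RNASEH1 was not higher.

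RNASEH1 was not higher in the libraries labelled RNase H1. If RNASEH1 counts the transgene, an exchange of the labels between the groups would need a high level in the libraries labelled Flag, and the ratio of mean RNASEH1 TPM, Flag over RNase H1, was 1.09. If transgene reads are not counted under RNASEH1, for instance from a recoded or bacterial sequence, this ratio says nothing about an exchange, and that case cannot be told apart from absent overexpression because the construct's sequence was not analysed here. A search for genes at 0 in both libraries labelled Flag and at 10 TPM or more in both others found 1, ENSG00000288708, which carries no name, so transgene reads counted outside RNASEH1 were neither found nor excluded.

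Immediate early genes were higher in the libraries labelled RNase H1. After removal of trends with GC content, exon length and span their median log2 fold change was 0.652, against 0.64 before, so these trends do not account for it. Between libraries of a group the median size of their differences was at most 0.0706. Cells of another type stay open and cannot be told apart from a response of the same cells: 5 fibroblast markers went both ways (median -0.12, SD 0.26), and 8 carcinoma epithelium markers had a median of 0.25 with 3 called higher and a list past the threshold (adjusted p = 0.0466). Handling, medium or transfection that differed between groups stays open, as does an effect of the overexpressed protein, and none of these was tested.

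A further hypothesis was that output of the ERK kinase pathway rose beyond the immediate early list. Of 25 further ERK output genes, ETV5 included, 12 were higher and 1 lower (median log2 0.48, camera p = 3.05e-07, adjusted p = 0.0794 over 3 lists with an estimated correlation). The list was written after the values of 6 of these genes had been seen, and the 19 others had 8 higher and 1 lower (median log2 0.38, camera p = 0.000248, p = 0.0577 with an estimated correlation). ETV4 rose from 0.84 to 4.3 TPM (1.52 ± 0.20), MAFF by 1.64 ± 0.15, HBEGF by 1.08 ± 0.11 and SPRED2 by 0.86 ± 0.12, and HMGA2 fell by 0.55 ± 0.07. ERK phosphorylation was not measured.

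Another hypothesis was that YAP and TAZ targets rose, because ANKRD1 and CCN2 (log2 1.44 ± 0.17) did. Of 19 targets outside the immediate early list, ANKRD1 included, 3 were higher and 0 lower, with a median log2 fold change of -0.0034. Their limma camera p was 0.0780, and 0.441 without ANKRD1 and GADD45B, whose values had been seen. The bound written for this test counted a p of 0.05 or more against the hypothesis, and by that bound it failed. A p that misses the threshold does not show that the genes did not differ, so the outcome is read as undecided, a reading adopted after the p was seen. AMOTL2 rose by 0.78 ± 0.09.

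The last hypothesis was that genes activated by MYC fall with MYC outside ribosome biogenesis. Of 33 such genes 1 was higher and 11 were lower (median log2 -0.14, camera p = 4.97e-05, adjusted p = 0.0794 over 3 lists with an estimated correlation). That is the direction lower MYC output would give, but MYC protein was not measured. Other causes of the fall stay open and were not tested. PTMA fell by 0.30 ± 0.03, PAICS by 0.33 ± 0.04 and CAD by 0.35 ± 0.06, and TYMS, which is also a G1/S gene, rose by 0.26 ± 0.06.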
